A study of Homo sapiens with 68 samples.

How the data were processed

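The series holds 68 samples of the human embryonic stem cell line H1 and of cells made from it. They comprise 12 chromatin immunoprecipitation (ChIP) samples, 12 input samples and 44 RNA samples. Only the KDM1A peak lists were analysed here, and the RNA and input samples were not analysed here. Per the labels, wild-type ChIP was made in embryonic stem cells (hESC, day 0, 3 samples), mesoderm at day 2 (2 samples), cardiac mesoderm at day 4 (1 sample) and cardiomyocytes at day 18 to day 20 (3 samples). KDM1A knockout cells that carried a rescue isoform were sampled as cardiomyocytes, with 2 samples for ubKDM1A and 1 for KDM1A+2a. Per the labels' protocols, chromatin was fixed with formaldehyde, sonicated and precipitated with an antibody to KDM1A or to a T7 tag. The label of each ChIP sample names the KDM1A antibody.

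Per the submitters' processing notes, the tools included Bowtie2 2.3.4.1, Picard, MACS2 2.2.4 and ChIPseeker 1.26.2, and the genome build was GRCh38. The notes used here give no order, filter or caller threshold. Each deposited file is a MACS2 narrowPeak list, with a position, a summit and 3 values per peak. The fold enrichment of a peak is a linear ratio of ChIP to control, as the authors' peak caller wrote it. The deposited p-value and q-value of a peak are on the −log10 scale, per the file format of the authors' peak caller. Fold and p were used only to describe, rank or filter peaks within a list, since they depend on the depth of that list. The files hold no read counts, so the depth of each library is unknown, and the number of peaks in a list moves with it.

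Each file held a single list, and its name gave its group but not which sample of the group it was. The 11 lists used were 2 of hESC, 2 of day 2, 1 of day 4, 3 of day 18 to day 20, 2 of the ubKDM1A rescue and 1 of the KDM1A+2a rescue. Lists of a group were given letters in order of peak number, with list a the shortest, and the letters serve only as names. 1 further list was not used, because its name gives no stage. The series text calls the ChIP experiments of a stage independent, but does not say whether they came from separate differentiations. It gives 2 experiments per stage apart from day 4 and the KDM1A+2a rescue, whereas the sample labels give 3 for hESC and for cardiomyocytes. The names of both hESC lists share a leading number, so whether these are separate experiments is not known. The n of 3 cardiomyocyte lists follows the labels. The permutation p-values therefore measure only the spread between these lists, which may be technical. Fisher's exact tests count genes, so their p-values do not measure the spread between lists. Per the labels, hESC ChIP samples were sequenced on 2 kinds of instrument and all other ChIP samples on 1 of these, so instrument and stage are partly confounded.

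Gene positions came from the RefSeq table of assembly GRCh38.p14, limited to the 19974 protein-coding genes of chromosomes 1 to 22 and X. The table gives the start and end of each gene and no transcript starts or strand. A gene was called bound in a list when a peak summit lay within 3 kb of either end of its span. This replaced the distance to a transcript start in the design that was set beforehand, and it takes in the far end of a gene as well as its promoter. Exon, intron and UTR positions were not used here. A stage's bound genes were those bound in every list of that stage. Genes that share a promoter share a peak and are not independent.

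The 20 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. All members of the lists were matched to the gene table, 1 pluripotency gene (CRIPTO) and 1 gene of oxidative phosphorylation (NDUFA4) through another symbol. Named genes were up to 4 members per gene list and stage, ranked by the mean within-list percentile of the authors' fold. Up to 10 genes, ranked likewise, were named for each set of lists compared, and a fixed group of regulators and cardiac genes was named whatever its values. Some genes that the rule selected are not reported here.

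Agreement between lists was the base-pair Jaccard index, the shared length over the joint length. The mean over pairs of the same wild-type stage minus that over pairs of different stages was tested by an exact permutation of the stage labels over the 8 wild-type lists. Gene lists were tested within each stage by Fisher's exact test, two-sided, members against all other genes. Benjamini-Hochberg adjustment covered the 80 tests of 20 lists at 4 stages. For the comparison of cardiomyocytes with earlier stages, the log2 odds ratio of being bound was taken within each list, with 0.5 added to each cell. Its mean over the 3 cardiomyocyte lists was compared with that over the 5 earlier lists by an exact two-sided permutation over 56 splits, adjusted over the 20 gene lists. The share of peaks near a gene end was compared in the same way. Overlaps expected of independent lists were the product of both gene numbers over all genes. Counts from the rescue lists and from hESC against day 2 were not tested, since so few lists allow no p under 0.05. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. The threshold was an adjusted p of 0.05.

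The steps were tested on simulated data. All 500 of 500 simulated gene calls were right. In simulated lists for day 18 to day 20, 78 of 80 gene lists with 8-fold odds were called, and 3 of 320 unchanged ones. These odds were set in each list separately, so the odds of being bound in every list of the stage were above 8-fold. In the simulated comparison of cardiomyocytes with earlier stages, the changed gene list (8-fold odds) had an unadjusted exact permutation p under 0.05 in 20 of 20 runs. Of the unchanged gene lists in those runs, 8 of 380 had one. Genes and lists were drawn independently in all runs, whereas real lists share peaks and real genes share promoters. The runs therefore give neither the power at weaker odds nor the rate of false calls in the real lists.

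Alternatives were windows of 1 kb and 10 kb, peaks with a −log10 q of at least 5, an equal number of strongest peaks per list, binding in at least 1 list of a stage, a reciprocal overlap of 50% and each list left out in turn. The equal number was 2710 for wild-type lists and 990 where rescue lists were compared, the length of the shortest list. Motif content and promoter sequence need a genome sequence and were not analysed here. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.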

Results

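KDM1A (LSD1) is a histone demethylase that acts with the RCOR corepressors, and its transcript is alternatively spliced. The ubKDM1A isoform is the ubiquitous form, and KDM1A+2a carries an additional exon. The series followed KDM1A on chromatin while H1 embryonic stem cells became cardiomyocytes, and in cardiomyocytes of KDM1A knockout cells that had been given back 1 isoform. The 2 hESC lists held 2710 and 3642 peaks, and the 2 day 2 lists 11121 and 30281. The day 4 list held 14637 peaks, and the 3 lists of day 18 to day 20 cardiomyocytes 3379, 4351 and 8182. The ubKDM1A rescue lists held 990 and 3664 peaks, and the KDM1A+2a rescue list 6128. Median fold enrichment, the authors' own value, lay between 3.99 and 5.11 in the 11 lists. Library depth is unknown, so peak numbers were not compared between stages. Day 4 and the KDM1A+2a rescue had no replicate.

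A first comparison asked whether lists of the same stage shared more sequence than lists of different stages. Genes bound in all 8 wild-type lists, at either end, numbered 260. By peak strength, these were led by PLXNA1, a semaphorin receptor (GRCh38 chromosome 3, 126983115 to 127037389), and the neighbours INCA1 and KIF1C. NR6A1, an orphan nuclear receptor that represses pluripotency genes, SLC11A1, a metal transporter, and ACTN3, an actinin of fast skeletal muscle, were also among them. The pairs CHP1 and EXD1, and C19orf85 and ISOC2, completed the leading 10. All of these 10 genes also carried peaks in the 3 rescue lists. A peak near at least 1 gene end was present for 12735 of 19974 genes in any wild-type list, and 7239 genes had none.

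Lists of the same stage overlapped more than lists of different stages. The mean Jaccard index was 0.167 within and 0.0958 between stages, a difference of 0.0711 (exact permutation p = 0.00952, n = 8 lists). The hESC pair reached 0.194, the day 2 pair 0.171 and the 3 cardiomyocyte pairs a mean of 0.157. Day 2 and day 4 lists overlapped with a mean of 0.158, and day 4 and cardiomyocyte lists with 0.126. hESC lists had means of 0.0818 with day 2, 0.0570 with day 4 and 0.0730 with cardiomyocyte lists, and these values move with list length. Without cardiomyocyte list b, the difference was 0.0745 and its exact permutation p 0.0571.

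**Figure D1:**
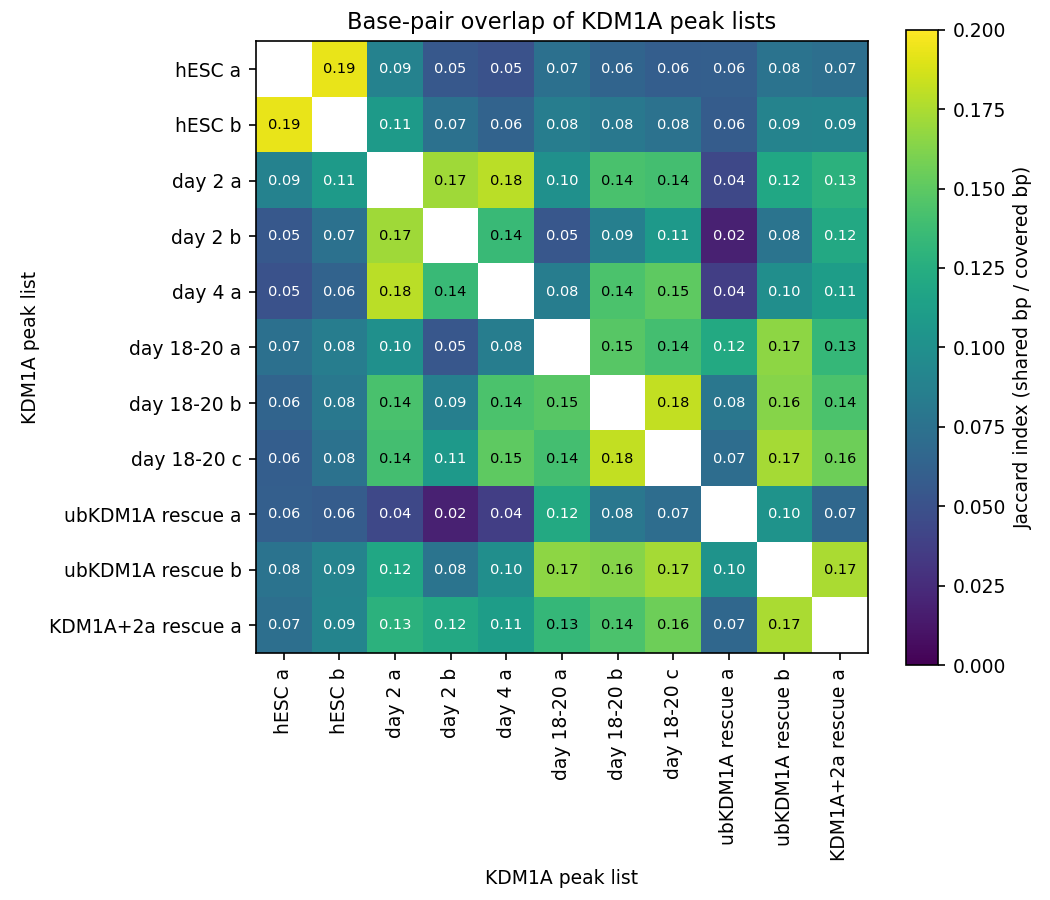
Base-pair Jaccard index (shared length over joint length, no unit) for each pair of the 11 KDM1A peak lists, with lists on both axes and the index as colour and printed value. The hESC pair had 0.194, and hESC against cardiomyocyte lists a mean of 0.0730.

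In hESC, KDM1A peaks lay at genes of neural fate and of cell signalling. Of 32 neural transcription factor genes, 8 were bound in both hESC lists (25.0%, against 4.89% of other genes), among them OLIG1 and OLIG2 of oligodendrocyte and motor neuron fate, EN2 of the midbrain and the POU factor POU3F2. Of 37 genes of the NOTCH, FGF and hedgehog pathways, 10 were bound (27.0% against 4.88%), including the NOTCH target HEY1, the ligand DLL4, the ERK phosphatase DUSP6 and the receptor FGFR1. Pluripotency genes were bound for 4 of 25 (16.0%), namely L1TD1, ZIC2, UTF1 and FGF4, with an adjusted p of 0.0924 (Fisher's exact test). None of the 392 olfactory receptor genes, taken as a background group, was bound. The neural (log2 odds ratio 2.75, adjusted p = 0.00109) and signalling lists (2.89, adjusted p = 9.4e-05) passed Fisher's exact test, and 5 lists were enriched at an unadjusted p under 0.05. With a window of 1 kb the signalling list had an adjusted p of 0.0515, and 7 lists were enriched without hESC list a and 4 without list b. Stage calls count genes bound in every list of a stage, so the number of lists differs between stages.

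At day 2, when the cells are mesoderm, 4712 genes were bound in both lists and 8 of the 20 gene lists were enriched. The NOTCH, FGF and hedgehog pathways led with 25 of 37 genes (adjusted p = 2.74e-07, Fisher's exact test), including FGFR1, FGF17, DUSP6 and the ETS factor ETV4. Neural transcription factors followed with 19 of 32 (exact adjusted p = 0.000155), among them OLIG1, EN2, SOX21 and NEUROG2. The WNT pathway, with the receptor gene FZD4 and the antagonist gene SFRP2, and the BMP and TGF-beta pathways, with ID1 and BMP2, each had 21 of 42 genes bound (exact adjusted p = 0.00136). Pluripotency genes were bound for 14 of 25 (exact adjusted p = 0.00323), among them L1TD1, CRIPTO, ZFP42 and KLF4. Partner complexes of KDM1A had 14 of 28 genes bound (exact adjusted p = 0.015), including the corepressor RCOR3 and the deacetylases HDAC1 and HDAC2. Neuronal effector genes, known targets of the repressor REST, had 16 of 36 (exact adjusted p = 0.0229), and cardiac transcription factors, with SRF, FOXF1, TBX2 and FOXC1, had 14 of 30 (exact adjusted p = 0.0287). Olfactory receptor genes were bound for 0 of 392. When each list was limited to the same number of strongest peaks, 2 gene lists were enriched at this stage.

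The single day 4 list, from cardiac mesoderm, bound 5643 genes, and 7 gene lists were enriched by Fisher's exact test. They were the NOTCH, FGF and hedgehog pathways (25 of 37, exact adjusted p = 1.03e-05), pluripotency (14 of 25, 0.0176), cardiac transcription factors (16 of 30, 0.0183), KDM1A partners (15 of 28, 0.0229), glycolysis (12 of 21, 0.0243), HOX genes (19 of 39, 0.0264) and the BMP and TGF-beta pathways (20 of 42, 0.0313). HOX genes, which pattern the body axis, included HOXB1, HOXD9, HOXD1 and HOXB13. Glycolysis genes included the enzymes GPI, PFKP, HK2 and PKM. Partner genes included PHF21A, a reader subunit of the KDM1A complex, and MTA3 of the NuRD complex. Limited to the same number of strongest peaks as the other stages, the day 4 list had 0 enriched gene lists and the log2 odds ratio was -1.06 for HOX and -0.15 for glycolysis genes. With a −log10 q of at least 5 these were -0.84 and -0.42. Of olfactory receptor genes, 1 of 392, OR2V2, was bound at day 4.

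In day 18 to day 20 cardiomyocytes, 978 genes were bound in all 3 lists. Cardiac transcription factors were bound for 6 of 30 (20.0% against 4.87% of other genes, log2 odds ratio 2.37, adjusted p = 0.0156, Fisher's exact test). Among the 6 were SRF, a regulator of muscle genes, the forkhead factor FOXC1 and the zinc finger factors GATA5 and GATA6. The NOTCH, FGF and hedgehog pathways had 7 of 37 bound (18.9% against 4.87%, log2 odds ratio 2.26, exact adjusted p = 0.0115), among them DUSP6, HES1, HES7 and ETV4. Sarcomere genes were bound for 4 of 29 (13.8%, exact adjusted p = 0.132), namely TNNT2, TNNC1, XIRP1 and MYBPC3. Olfactory receptor genes were bound for 0 of 392. With peaks of a −log10 q of at least 5, 0 gene lists were enriched at this stage, and without cardiomyocyte list a 5 were.

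Cardiomyocytes were then set against all earlier stages, to ask which gene groups differed in how often they carried a peak. Sarcomere genes, which encode the contractile apparatus, carried peaks in 9, 6 and 12 of 29 members in the cardiomyocyte lists, and in 2 and 1 in hESC, 5 and 13 at day 2 and 6 at day 4. Their mean log2 odds ratio was 1.34 ± 0.51 (SD, n = 3) in cardiomyocytes and -0.67 ± 0.47 (SD, n = 5) earlier, a difference of 2.01. Neural transcription factors went the other way, with 12 and 16 of 32 members in hESC, 19 and 29 at day 2, 13 at day 4 and 1, 6 and 4 in cardiomyocytes. Their mean log2 odds ratio was -0.54 ± 1.08 (SD, n = 3) against 2.21 ± 0.82 (SD, n = 5), a difference of -2.75. Each of these contrasts separated all 3 cardiomyocyte lists from all 5 earlier lists, which gives the smallest exact permutation p of 56 splits, 0.0357.

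The same separation held for 6 further gene lists, all lower in cardiomyocytes. The differences in mean log2 odds ratio were -2.09 for HOX genes (-1.76 against 0.33) and -1.89 for early mesoderm genes (-0.03 against 1.86). They were -1.40 for pluripotency genes (0.53 against 1.94), -1.31 for endoderm genes (-0.40 against 0.91) and -0.89 for endothelial and haematopoietic genes (-0.48 against 0.41). The NOTCH, FGF and hedgehog pathways differed by -0.32 and had high odds in both (2.15 against 2.48). For these 8 of 20 gene lists, 7 lower and 1 higher, the exact permutation p was 0.0357 and the adjusted p 0.0893, so 0 lists passed the adjusted threshold. At this smallest p, adjustment over 20 lists can be passed only if most of them separate the stages fully. The 8 gene lists became 2 with an equal number of strongest peaks, where the neural difference was -2.35 (exact permutation p = 0.107), and 2 with a 1 kb window. The difference for endothelial and haematopoietic genes was 0.34 with a −log10 q of at least 5 and 0.21 with an equal number of peaks, and that for endoderm genes was 0.0034 with the stricter q.

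The other 12 gene lists did not separate the stages. Cardiac transcription factors had mean log2 odds ratios of 2.02 ± 0.59 (SD, n = 3) in cardiomyocytes and 1.53 ± 0.35 (SD, n = 5) earlier, with an exact permutation p of 0.214. KDM1A partner genes had 1.60 against 1.41, WNT genes 1.31 against 1.28, and BMP and TGF-beta genes 1.46 against 1.62. Glycolysis genes had 1.70 against 1.10, calcium handling and ion channel genes 1.08 against 0.76, and the list of smooth muscle, fibroblast and epicardium 0.76 against 0.58. Neuronal effectors had -0.05 against 1.08 (exact permutation p = 0.179), cell cycle genes 0.13 against 0.50 and oxidative phosphorylation genes -0.36 against -0.88. Cytosolic ribosomal protein genes had -0.08 against 0.03, and olfactory receptor genes -7.16 against -6.47. In each cardiomyocyte list 0 of 392 olfactory receptor genes had a peak, so their value there is set by the 0.5 added to each cell. The exact permutation p of these 12 lists lay between 0.179 and 0.893.

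**Figure D2:**
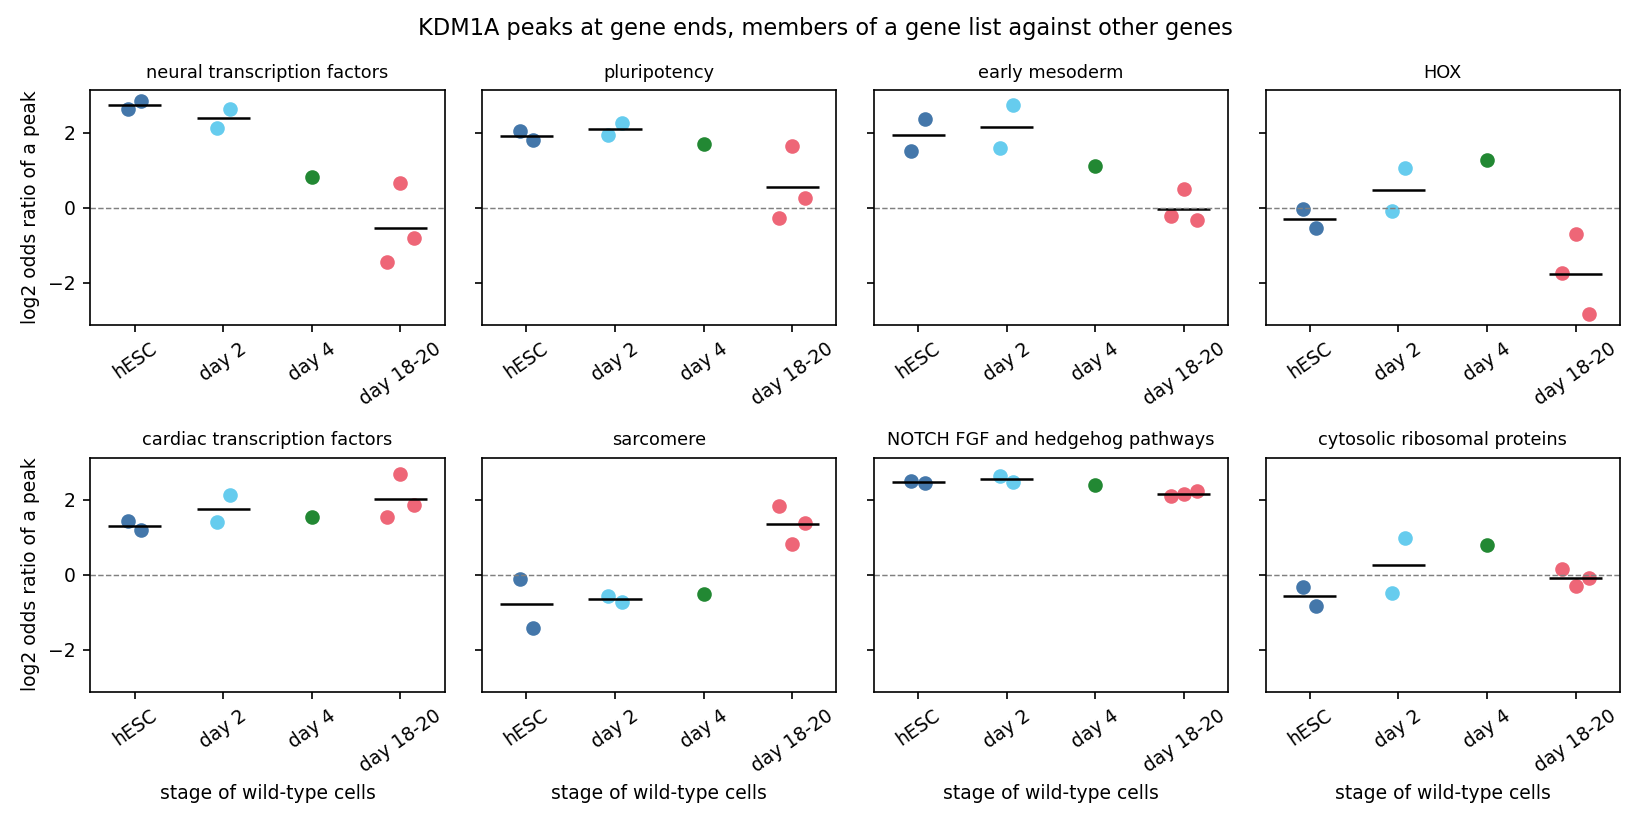
Log2 odds ratio of carrying a KDM1A peak near a gene end, members of a gene list against all other protein-coding genes (vertical axis), by wild-type stage (horizontal axis), with each point a peak list and each line the mean of a stage with several lists. Sarcomere genes had a mean of 1.34 in the 3 cardiomyocyte lists and -0.67 in the 5 earlier lists, and neural transcription factors -0.54 and 2.21.

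Single genes that followed the same division were few. Only 6 genes were bound in all 3 cardiomyocyte lists and in no earlier list. Among them were MAB21L2, a developmental gene, P4HA2, a collagen prolyl hydroxylase, the ubiquitin ligase gene RNF149, the sialic acid acetyltransferase gene CASD1 and LOC124903571. In the other direction, 90 genes were bound in all 5 earlier lists and in no cardiomyocyte list. By peak strength these were led by the tight junction gene TJP3 and the zinc finger gene ZNF536, with POU4F2, FEZF2 and NEUROD6, transcription factors of neurons, NFATC4, SMOC1 and NKAIN4. OVOL1, an epithelial transcription factor, and LOC124902693, which share a peak, completed the leading 10. EOMES, a driver of mesendoderm, was among the 90. From the same number of strongest peaks in every list, the counts were 43 and 18. The first count was 33 without day 2 list b, 13 without the day 4 list, and 17, 24 and 10 without cardiomyocyte lists a, b and c. The second was 197 and 164 without hESC lists a and b, 188 without day 4 and 141 without cardiomyocyte list c.

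The share of peaks whose summit lay near a gene end was 57.0% ± 5.14 (SD, n = 3) in cardiomyocytes and 50.1% ± 9.33 (SD, n = 5) earlier. The difference of 6.93 percentage points was within the spread between lists (exact permutation p = 0.286, smallest possible 0.0357), and it was 2.99 points when each list was limited to equally many strongest peaks. The earlier lists were not alike. The share was 59.0% and 61.1% in the hESC lists, and 61.6%, 58.0% and 51.5% in cardiomyocyte lists a, b and c. It was 46.1% and 43.8% at day 2 and 40.5% (exact 95% interval 39.7% to 41.3%) at day 4. The lower earlier mean thus came from the day 2 and day 4 lists, which are the longest, and not from hESC.

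The step from hESC to day 2 was described by counts alone. Both day 2 lists and neither hESC list held peaks at 2651 genes, and 12 genes had the reverse. The former were led by ANK1, which encodes ankyrin, the E protein gene TCF3, the arginine sensor gene CASTOR1, TCF20 and the metalloproteinase gene MMP17. KIAA1755, FBXO2, ZNF174, SPOCD1 and the heparan sulfate enzyme gene NDST1 followed. All of these but NDST1 also carried a peak in the day 4 list. Of the 983 genes bound in hESC, 765 were bound at day 2, where 232 were expected of independent lists, and 286 in cardiomyocytes, where 48.1 were expected. Day 4 shared 875 genes with the 978 of cardiomyocytes (276 expected). The count of 2651 was 251 with an equal number of strongest peaks, 1486 with a −log10 q of at least 5 and 8382 without day 2 list a. The day 2 lists bound 4994 and 11502 genes in all, and the hESC lists 1800 and 2463. The counts of 2651 and 12 therefore move with list length and do not show a change of stage.

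Regulators of pluripotency, mesoderm and the heart were described gene by gene, without a test between these groups. POU5F1, a core pluripotency factor, carried a peak in day 2 list b alone, and NANOG in day 2 list b, day 4 and the KDM1A+2a rescue. SOX2 carried one in hESC list b, day 2 list b and day 4. Early mesoderm genes varied. SP5, a WNT target, was bound in all 8 wild-type lists, FOXH1 in hESC list b, day 2 list b, day 4 and cardiomyocyte lists b and c, TBX6 in both day 2 lists, day 4 and cardiomyocyte list c, and SNAI2 in both hESC lists, day 2 list b and cardiomyocyte list a. EOMES (chromosome 3, 27715953 to 27722713) had one in all 5 earlier lists, TBXT in 4 of these and MESP1 in 4, and none of these 3 genes had one in a wild-type cardiomyocyte list, while EOMES had one in ubKDM1A rescue list b. MIXL1 had a peak in day 2 list b alone. GATA4, a cardiac zinc finger factor (chromosome 8, 11676935 to 11760002), had a peak in day 2 list b, at day 4, in all 3 cardiomyocyte lists, in ubKDM1A rescue list b and in the KDM1A+2a list. Its cardiomyocyte summits at 11676211, 11676255 and 11676328 lay 724, 680 and 607 bp outside the lower end of the gene span.

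TNNT2, the cardiac troponin T gene (chromosome 1, 201359014 to 201377680), had a peak in day 2 list b, at day 4, in all 3 cardiomyocyte lists and in all 3 rescue lists. Its cardiomyocyte summits lay at 201377295, 201377308 and 201378009, with folds of 6.75, 9.37 and 6.66. HAND1 had a peak in day 2 list b, at day 4, in cardiomyocyte lists b and c, in ubKDM1A rescue list b and in the KDM1A+2a list. ISL1 had one in day 2 list b, cardiomyocyte list c and the KDM1A+2a list, TBX5 in cardiomyocyte list b alone, and NKX2-5 in day 2 list b and at day 4. HAND2 had one in day 2 list b and the KDM1A+2a list. No list had a peak within 3 kb of an end of MEF2C, MYH6, MYH7 or TTN. KDM1A itself had a peak in day 2 list b and cardiomyocyte lists b and c. RCOR1, its corepressor partner, had one in 7 of the 8 wild-type lists, all but cardiomyocyte list b. It also had one in ubKDM1A rescue list b and the KDM1A+2a list. REST had one in hESC list a, both day 2 lists, day 4, cardiomyocyte list b and ubKDM1A rescue list b.

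The rescue lists addressed where each KDM1A isoform, returned alone to knockout cells, was found in cardiomyocytes. Of the 978 genes bound in all 3 wild-type cardiomyocyte lists, ubKDM1A rescue list a shared 340 (34.8%, exact 95% interval 31.8% to 37.8%) and list b 716 (73.2%, 70.3% to 76.0%). The KDM1A+2a rescue list shared 770 (78.7%, 76.0% to 81.3%). Independent lists would share 32.8, 136 and 217 genes. All 3 rescue lists held 416 genes in common, and 284 of these were bound in all 3 wild-type cardiomyocyte lists, TNNT2, SRF and the NOTCH target HES7 among them. Both ubKDM1A lists and not the KDM1A+2a list held 53 genes, of which 16 were bound in all wild-type cardiomyocyte lists. These were led by SHD, the trafficking gene TRAK1, SPOCD1, ANKRD9, SDHAF2, the neighbours ANGPTL6, PPAN and PPAN-P2RY11, and MAP4K2 and MEN1, which encodes the scaffold protein menin. The KDM1A+2a list and neither ubKDM1A list held 2586 genes, 137 of them bound in all wild-type cardiomyocyte lists. Among those leading these were ERF, an ETS repressor, ZSCAN12, FAM20C and GREB1, with the overlapping genes FMC1, FMC1-LUC7L2 and LUC7L2, then MLLT1 and MAFK. The counts of 53 and 2586 rest on unlike rules, 2 lists against 1, and on unlike list lengths. The ubKDM1A lists bound 669 and 2778 genes in all, and the KDM1A+2a list 4428. The genes named are therefore not shown to be specific to an isoform.

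The mean ubKDM1A share was 54.0%, which is -24.7 percentage points from the KDM1A+2a share. No test was made, since 2 lists against 1 give 3 splits, and the ubKDM1A lists differed from each other by more than their mean did from KDM1A+2a. With the 990 strongest peaks of each list the shares were 67.0% and 84.4% for ubKDM1A and 76.2% for KDM1A+2a, a difference of -0.51. Without ubKDM1A list a the difference was -5.52, and without list b -44.0.

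**Figure D3:**
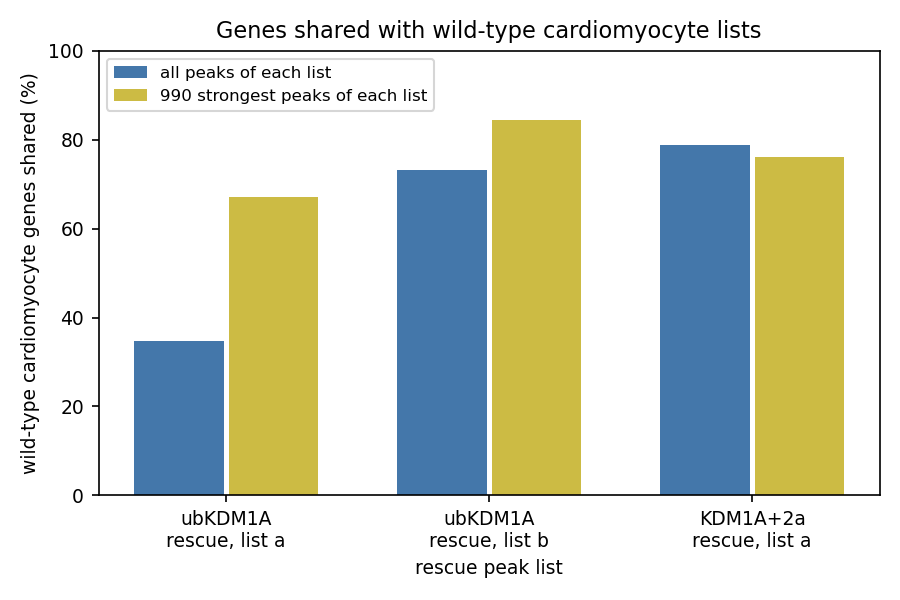
Percent of wild-type cardiomyocyte genes (vertical axis) that also carried a peak in each rescue list (horizontal axis), with bars for all peaks (978 genes) and for the 990 strongest peaks of each list (294 genes). The KDM1A+2a list had 78.7% with all peaks, above both ubKDM1A lists, and 76.2% with equal numbers, between the ubKDM1A lists at 67.0% and 84.4%.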

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

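The tests of list length, sequencer and transcription were chosen after the results were seen. The split counts for single genes were planned beforehand, but the limit by which they were judged was written after the results were seen. For gene lists, the split count and its limit were set before. A search for peaks of very high −log10 p at a low fold was limited to peaks outside the gene-end comparisons and in a single list. It found a peak on chromosome 3 (93470402 to 93470767, summit 93470581, GRCh38). This peak was in ubKDM1A rescue list a alone, with 0 of the 10 other lists holding it, as the search required. Its −log10 p was 704, where the next highest of that list was 98.0, while its fold was 2.19, the lowest of that list. It lay 402 kb from the nearest protein-coding gene end. The other ubKDM1A list lacked this peak, so it is not read as a site of that isoform, and its cause was not tested.

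With all peaks, more neural transcription factor genes carried a peak in each earlier list than in any cardiomyocyte list. The greater length of a list does not account for the hESC part, since the hESC lists held at least 12 members with all peaks and cardiomyocyte lists b and c, which are longer than both, at most 6. Trimming to equal numbers (at least 10 against at most 5) adds little, because it shortens mainly the cardiomyocyte lists. The sequencer cannot be told apart from stage, since day 2 and day 4 lists, which share the cardiomyocyte instrument, held at least 13 members with all peaks (cardiomyocytes at most 6) but as few as 3 with equally many, the measure adopted after the first was seen. The higher counts of day 2 and day 4 may therefore rest on their longer lists, and the hESC difference may reflect stage or instrument.

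Sarcomere genes had higher odds of a peak, relative to other genes, in cardiomyocyte than in earlier lists, with an adjusted p of 0.0893 (exact permutation), although by number day 2 list b held 13 of 29 and the cardiomyocyte lists at most 12. With an equal number of strongest peaks the difference of the mean log2 odds ratio was 3.16, and the lowest cardiomyocyte list lay 1.63 above the highest earlier list, which argues against list length. Cytosolic ribosomal protein genes had a mean log2 odds ratio of -0.0779 in the wild-type cardiomyocyte lists, where sarcomere genes had 1.34. For these lists only, that argues against signal at all highly transcribed genes alike, but it rests on the ribosomal list alone. Glycolysis genes had 1.70 in the same lists, above the sarcomere mean, and oxidative phosphorylation genes -0.36. Signal at some highly transcribed genes therefore stays open. In the rescue cardiomyocytes the order was mixed. Ribosomal protein genes had 0.88 and 0.17 in ubKDM1A lists a and b, and 0.68 in the KDM1A+2a list. Sarcomere genes had 0.60, 0.78 and -0.04 in the same lists. Stage stays open as an explanation and was not tested further, and no list had a peak near an end of MYH6, MYH7 or TTN. Signal at genes transcribed only in heart was not tested, since RNA was not analysed here.

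The KDM1A+2a rescue list shared more wild-type cardiomyocyte genes than the mean of the ubKDM1A lists. With an equal number of strongest peaks its share was 76.2%, between the ubKDM1A shares of 67.0% and 84.4%, so that the difference may come from list length. With 1 KDM1A+2a list, an isoform difference stays open and untested.

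Other splits of the 8 wild-type lists into 3 and 5 were counted. For genes bound in all 3 lists and none of the 5, 25 of 56 splits gave as many as the real 6, and the highest other gave 498, so chance cannot be excluded with all peaks. That highest split set both day 2 lists and day 4, the 3 longest lists, against the rest, which points to a structure by list length. With an equal number of strongest peaks, 2 of 56 splits gave as many as the real 43, but the other of these, both hESC lists with day 2 list b, gave 99, so chance is not taken as excluded there either. For genes bound in all 5 and none of the 3, 3 of 56 splits gave as many as the real 90, with 220 the highest other, so chance cannot be excluded, nor with equal numbers, where 4 of 56 gave as many as the real 18 (highest other 21). For gene lists at an unadjusted exact permutation p under 0.05, 1 of 56 splits, the real one, gave 8 with all peaks, with 3 the highest other. The splits treat the 8 lists as exchangeable, but lists of the same stage overlapped more and may be technical repeats. Few other splits keep stages whole, so chance is not taken as excluded for that count either. With an equal number of strongest peaks, 7 of 56 splits gave as many as the real 2, with 4 the highest other, so the real split was not extreme there.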

How the results depend on the processing

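Chosen after seeing the data were the gene span extended by 3 kb, the 100 strongest peaks and the discordant-gene test. Not run, for lack of a genome sequence and transcript starts, were the motif comparison, strata of CpG content and a single start per gene. No paired analysis was possible because the numbers in the names of the peak lists could not be matched to the labels' replicate numbers. With a list left out, the permutation contrast of gene lists allows no p under 0.05, and depth, which limits peak numbers, is unknown. Where no reason is given below, the cause was not tested.

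The overlap within stages kept its direction under all alternatives run, and the difference lay between 0.0537 and 0.0819 with a list left out. Without cardiomyocyte list b it was 0.0745 (exact permutation p = 0.0571). The mean share of peaks near gene ends stayed higher in cardiomyocytes than in the pooled earlier lists. With all peaks, these mix high hESC shares with low day 2 and day 4 shares. The difference was 4.53 to 9.71 points with a list left out and 2.99 with an equal number of strongest peaks. The number of gene lists past the adjusted threshold between cardiomyocytes and earlier stages was 0 in every setting, but with so few splits it can exceed 0 only if most of the 20 lists separate fully, so this says nothing about stability. The discordant-gene test of hESC against cardiomyocytes also gave 0, with neural factors at 8 against 1 gene (Fisher's exact test, adjusted p = 0.613).

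With a −log10 q of at least 5 the median cardiomyocyte list held 1941 peaks in place of 4351, and fewer peaks by construction. Gene lists at an unadjusted p in that contrast were then 5 in place of 8. Enriched gene lists were 0 in cardiomyocytes, 5 at day 2 and 1 at day 4. Genes bound at day 2 and not in hESC were 1486, those of cardiomyocytes alone 1 and those of earlier lists alone 37. Log2 values that turned direction were 0.0034 for endoderm and 0.34 for endothelial genes in the contrast, and -0.84 for HOX and -0.42 for glycolysis genes at day 4. With an equal number of strongest peaks, gene lists at an unadjusted p were 2, and enriched lists 1 in cardiomyocytes, 2 at day 2 and 0 at day 4. The gene counts were then 251, 43 and 18, and the turned values 0.21 for endothelial genes in the contrast, -1.06 for HOX and -0.15 for glycolysis at day 4.

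With a 1 kb window, gene lists at an unadjusted p were 2, enriched lists 1 in hESC, 3 at day 4 and 1 in cardiomyocytes, and genes of earlier lists alone 57. With 10 kb these gene lists were 5, and enriched lists 4 in hESC and 6 in cardiomyocytes. With the extended gene span they were 5, 4 in hESC and 5 in cardiomyocytes. Counting genes bound in at least 1 list, enriched lists were 8 in hESC and 7 in cardiomyocytes.

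With a list left out, enriched gene lists were 4 (without list b) to 7 (without list a) in hESC, 9 at day 2 and 3 to 5 in cardiomyocytes, 5 without list a. Genes bound at day 2 and not in hESC were 2911 to 8382, the highest without day 2 list a. Genes of cardiomyocyte lists alone were 6 to 33, the highest without day 2 list b, and those of earlier lists alone 92 to 197, the highest without hESC list a. The rescue difference was -44.0 to -5.52 points, and with an equal number of peaks -0.51. Of 230 named genes, the number of lists with a peak was the same for 73 with the stricter q, 57 with equal numbers, 152 with 1 kb, 180 with 10 kb and 204 with the gene span.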

Other observations

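The peaks described next were singled out after their values were seen, while the test on genes of epithelial-mesenchymal transition was set before its result. The same 4 genes lay nearest the strongest peaks by p in both hESC and both day 2 lists: PKDCC, a secreted kinase gene, ZEB1, a repressor that drives epithelial-mesenchymal transition, VIM, which encodes the intermediate filament vimentin, and INAFM2. PKDCC had a fold of 147 in hESC list a and 53.7 in list b, ZEB1 73.9 and 93.8, VIM 42.9 and 76.8, and INAFM2 47.5 and 64.5. Within the day 4 list, PKDCC ranked 1533 and ZEB1 2519 of 14637 peaks, INAFM2 ranked 31 with a fold of 22.6, and no peak overlapped the VIM peak. In cardiomyocyte lists a, b and c, ZEB1 ranked 19 of 3379, 287 of 4351 and 1536 of 8182, with folds of 16.3, 4.84 and 5.70. Ranks from lists of different lengths do not show a change.

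Overlaps were also counted among the 100 strongest peaks of each list. The hESC lists shared 75 of them, the day 2 lists 59, and hESC and day 2 lists between 27 and 37. hESC and cardiomyocyte lists shared between 8 and 19, and the 3 cardiomyocyte lists between 50 and 58 per pair. Day 4 shared between 47 and 54 with cardiomyocyte lists, and day 2 between 34 and 51. Day 2 and day 4 shared between 45 and 52. Cardiomyocyte lists shared between 45 and 60 with the ubKDM1A lists and between 52 and 57 with the KDM1A+2a list.

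As a hypothesis from these leading peaks, KDM1A in hESC may favour genes of epithelial-mesenchymal transition in general. Of 18 further genes of that process, 3 were bound in both hESC lists (CDH2, OVOL2 and EPCAM, 16.7% against 4.91% of other genes), where 0.886 were expected. Fisher's exact test, two-sided, gave p = 0.0558. The bound set beforehand counted any p of 0.05 or more against the hypothesis, and by that bound the hypothesis failed. After p was seen it was instead left undecided, since 18 genes with 0.886 expected give the test little power. CDH2, OVOL2 and EPCAM also had a peak in both day 2 lists. So had others of the 18, among them CDH1 and GRHL2, while TCF4 and KLF8 had none in any list. Such peaks are thus not particular to hESC, and the longer day 2 lists were not tested for these genes.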
